A study of Nicotiana tabacum with 20 samples.

How the data were processed

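Leaf RNA of 20 tobacco libraries was measured: 4 each of wild-type plants (WT), empty-vector plants (C), hairpin line 8 in the T1 generation (HP8_T1), hairpin line 1 in the T1 generation (HP1_T1) and its selfed T2 progeny (HP1_T2). Per the labels, total RNA was extracted with lithium chloride and made into libraries with the SOLiD total RNA kit. The aligner, its settings and the build of the reference are not given in the sources used here. The identifiers in the files are UniGene identifiers, and 0 of the 24069 matched a gene, synonym or accession among the 79372 genes of the reference table at hand.

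Per the file headers, the authors deposited read counts per feature in 2 ways, all gene reads and unique gene reads, together with feature lengths, RPKM and values derived from it. The deposited RPKM values equalled total reads divided by feature length and by the sum of total gene reads in the library. The authors' transformed score equalled the square root of the RPKM, and their normalized score was that square root scaled to the same sum in every library, as checked on the values. The authors also deposited differences, fold changes and p-values of a comparison of wild type with the pooled hairpin libraries, on the normalized scores, and of wild type with the empty-vector libraries, on the transformed scores, per the file headers. The WT columns of both tables were identical, so all 20 libraries could be placed in 1 fit. Total gene reads were analysed; unique reads made up 99.0% to 99.7% of them.

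Group comparisons used edgeR 4.0.16 in R 4.3.3 on the deposited counts: TMM factors, filterByExpr with a minimum count of 10 and the group as the only term, quasi-likelihood F tests, and a Benjamini-Hochberg adjusted p of 0.05. Each deposited table was fitted whole (8 libraries with 2782 features, 16 libraries with 7052 features), and comparisons of hairpin with empty-vector plants, sets of features across groups and overlaps used 1 fit of all 20 libraries (7126 features). The common biological coefficient of variation between libraries of a group was 8.06%, 8.86% and 8.91% in these fits. The comparisons, the tests and the settings of the alternatives were fixed before the data were examined, except for unique reads, 4 further scalings, the fit of all 20 libraries for comparisons with WT, the abundance classes, the sets of features across groups and the thinning, which were chosen after seeing the data. The 6 scalings were TMM, DESeq2 size factors, library totals, totals outside the most abundant feature, totals outside the 100 most abundant features, and the upper quartile. DESeq2 1.42.0 gave an alternative test.

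The rule for named features, fixed in advance, took those with the largest fitted change among features past the threshold whose libraries did not overlap between the groups and that had a mean of at least 20 reads in the higher group. It also asked for a description of the product, and lists of genes by function and of markers of cell types were to be tested. The files do not pair identifiers with names, so these conditions and lists could not be applied. The rule also asked for more features and for further comparisons. Only 2 features that rose and 2 that fell in the hairpin mean against WT are named, a cut that was not part of the rule. A fold against a group without reads sets that group at 3 reads over its 4 libraries.

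Single values per library were compared with two-sided exact permutation tests in Python 3.11.15 with scipy 1.17.1, adjusted over the 9 comparisons of each measure. Libraries were thinned without replacement in 20 draws to 199341 reads outside the most abundant feature. Libraries of the same group were compared in 30 pairs; chi-square per degree of freedom over features was 1.24 to 2.05, and the largest p was 5.52e-17, so no library was taken for another deposited again. Repeat libraries or runs of 1 RNA sample would exceed counting noise too and are not excluded. Overlaps of calls were set beside 20 simulations in which all libraries, WT included, were drawn from the WT mean, and beside independent lists.

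The fits were tested on simulated counts drawn from the real means, library sizes and dispersions with 200 features changed, 100 of them 2-fold and 100 of them 4-fold. In the C against WT fit (2782 features), 82% and 95% of 2-fold and 4-fold changes were recovered, with 2.75% of calls false. In the hairpin mean against WT (7052 features) these were 68% and 91% with 3.05% false, in HP1_T2 against HP1_T1 (7052 features) 52% and 91% with 3.38%, and in the hairpin mean against C (7126 features) 47% and 95% with 3.40%. The simulated changes were few, with as many rises as falls. In the real data, 35.0% to 56.0% of features were called in these comparisons, and the makeup of the libraries shifted between groups. The simulated false shares therefore do not carry over to the real calls. Depth outside the most abundant feature ranged from 199341 to 647426 reads per library, and this limits what can be seen of rare transcripts, most of all in C.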

Results

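RNA abundance was measured in leaves of *Nicotiana tabacum* (tobacco) in which the control of the retrotransposon Tnt1 had been altered with a transgene. Tnt1 is a mobile element of tobacco that copies itself through RNA, and the transgene was a hairpin made from a fragment of its reverse transcriptase sequence. The 20 libraries fell into 5 groups of 4: wild-type plants (WT), plants transformed with the empty vector (C), hairpin line 8 in the T1 generation (HP8_T1), hairpin line 1 in the T1 generation (HP1_T1) and the selfed progeny of that line (HP1_T2). Plants were 45 days old and were grown in vitro under 14 h of light at 24 °C. The series asked how far gene expression changes when retrotransposon control is altered. Counts were given for 24069 UniGene sequences, called features here, and the files do not pair these identifiers with gene names. The retrotransposon, the transgene and named gene families could therefore not be picked out. Total gene reads per library ranged from 1958952 to 3638494, and 3675 features had no read in any library. The labels do not say that the 4 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which can be technical.

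A single feature of 625 bases, singled out after its values were seen, held most of the reads in every library. The libraries were made from total RNA, and whether this feature is messenger, ribosomal or plastid RNA is not given in the sources used here, so its share, and any scale set by library totals, cannot be read as a property of messenger RNA alone. It took 84.3% ± 1.71 of gene reads in WT, 89.4% ± 1.09 in C, 76.2% ± 1.87 in HP8_T1, 77.9% ± 1.83 in HP1_T1 and 78.7% ± 2.04 in HP1_T2 (SD, n = 4 each). Its share was thus higher in C than in WT and lower in each hairpin group than in both controls, with no overlap between the groups' libraries (two-sided exact permutation test, p = 0.0286 for each, the smallest that 4 libraries against 4 allow; 0.0367 after Benjamini-Hochberg adjustment over 9 comparisons). Between the hairpin groups the libraries overlapped in this share (exact permutation p = 0.571 between generations and p = 0.257 between lines). The replicate numbers ordered the share alike in all 5 groups, and within the 4 numbers HP8_T1 differed from HP1_T1 by −1.51 to −1.87 percentage points and HP1_T2 differed from HP1_T1 by 0.504 to 1.08. Each of these differences had 1 sign in 4 of 4 numbers (exact paired permutation p = 0.125, the smallest that 4 pairs allow). Outside this feature, 502229 ± 91256 reads remained in WT, 258725 ± 41066 in C, 573815 ± 82931 in HP8_T1, 543794 ± 97417 in HP1_T1 and 456949 ± 32987 in HP1_T2 (SD, n = 4 each), and the precision of every other feature rests on these reads.

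The remaining reads were spread over more features in the transgenic groups than in WT. The next most abundant feature, of 868 bases, took 38.3% ± 1.32 of the remaining reads in WT, 31.6% ± 1.21 in C, 31.5% ± 0.915 in HP8_T1, 21.1% ± 0.713 in HP1_T1 and 29.0% ± 0.920 in HP1_T2 (SD, n = 4 each). Each transgenic group lay below WT in all libraries (exact permutation p = 0.0286, adjusted 0.0321). Features beyond the 1000 most abundant took 15.7% ± 0.279 of the remaining reads in WT, 22.5% ± 0.417 in C, 24.2% ± 0.313 in HP8_T1, 29.4% ± 0.114 in HP1_T1 and 23.2% ± 0.239 in HP1_T2. After every library was thinned to 199341 reads outside the most abundant feature, a mean of 10243 features had a read in WT (libraries from 10193 to 10326), 12022 in C (11950 to 12129), 12533 in HP8_T1 (12487 to 12602), 13462 in HP1_T1 (13404 to 13502) and 12281 in HP1_T2 (12221 to 12329), with n = 4 in each group. All transgenic groups exceeded WT, and HP1_T1 exceeded its progeny HP1_T2, without overlap (exact permutation p = 0.0286, adjusted 0.0286). Thinned to 77002 reads outside the 100 most abundant features, the means were 10908 in WT, 11963 in C, 12346 in HP8_T1, 12651 in HP1_T1 and 12191 in HP1_T2. The difference from WT then fell from 3219 to 1743 features in HP1_T1, and that of HP1_T2 from HP1_T1 went from −1181 to −460.1, still without overlap (exact permutation p = 0.0286).

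**Figure D1:**
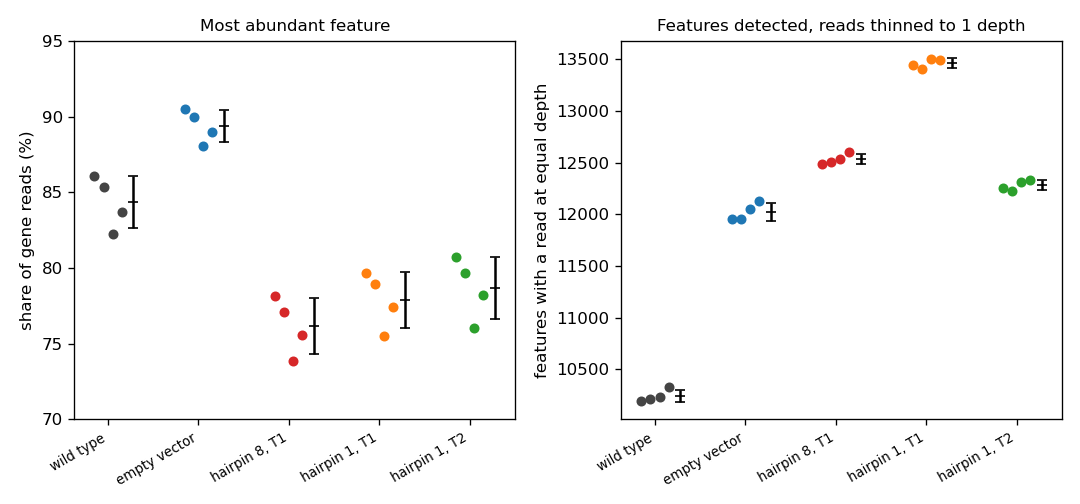
Left, share of gene reads taken by the most abundant feature in each library, in percent, by group; right, number of features with at least 1 read after thinning to 199341 reads outside that feature. Points are libraries and bars are mean ± SD (n = 4); neither axis starts at 0. The 4 C libraries lie above the 4 WT libraries on the left, the 12 hairpin libraries lie below both, and WT detects the fewest features on the right.

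The libraries separated by group along principal components 1 and 2 of the log2 normalised read counts. Component 1 held 41.7% of the variance and placed C between WT and the hairpin groups, and component 2 held 14.8% and set C apart. Pairs of libraries within a group correlated across features at 0.858 to 0.945. WT libraries correlated at 0.709 to 0.743 with C, at 0.593 to 0.615 with HP8_T1, at 0.603 to 0.628 with HP1_T1 and at 0.646 to 0.662 with HP1_T2, and HP1_T1 at 0.810 to 0.831 with HP1_T2. These correlations are across features, which are not independent replicates.

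**Figure D2:**
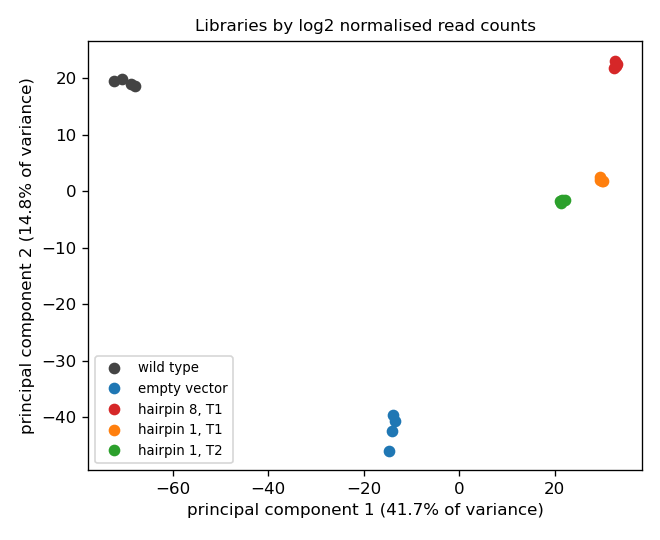
Principal components 1 and 2 of the log2 normalised read counts of 7126 features; each point is a library and colours mark the 5 groups. The 4 libraries of each group lie together, WT at the far left and the 3 hairpin groups at the right, with C between them on component 1.

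The comparison of empty-vector with wild-type plants addressed what transformation and regeneration go with when no hairpin is present. Of 2782 features tested in these 8 libraries, 739 rose and 787 fell in C. At least 2-fold changes made up 381 of the rises and 492 of the falls, and at least 4-fold changes 86 and 150. The median log2 change was 1.02 among features that rose and −1.20 among those that fell, with a median SE of 0.27. Among the 90 features ranked 11 to 100 in abundance, 27 were higher and 51 lower in C than in WT. These counts are from the fit of all 20 libraries with TMM scaling. The calls are from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. When the reads outside the most abundant feature set the scale, 1276 rose and 472 fell; 614 rose and 472 fell under all 6 scalings tried. The fit of all 20 libraries, which tested 7126 features, called 1398 higher and 1495 lower.

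Hairpin plants differed from wild type in 3949 of the 7052 features tested, and a set of features changed alike in both lines and both generations. Of these, 2110 rose and 1839 fell in the mean of the 3 hairpin groups against WT, with 1597 rises and 1139 falls of at least 2-fold and 698 and 384 of at least 4-fold. The median log2 change was 1.52 among features that rose and −1.19 among those that fell (median SE 0.28). Group by group, 2125 rose and 1775 fell in HP8_T1, 2135 and 1729 in HP1_T1, and 2006 and 1707 in HP1_T2. In the fit of all libraries, 1133 of 7126 features (15.9%) were higher than WT in each of the 3 hairpin groups and 1061 (14.9%) were lower in each. Their median log2 changes against WT were 2.16, 2.14 and 2.07 for the higher set, and −1.66, −1.67 and −1.57 for the lower set, in HP8_T1, HP1_T1 and HP1_T2 in that order.

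The direction of these calls depended on how libraries were scaled. The median log2 change of all tested features in the hairpin mean against WT was 0.12 with TMM scaling, 0.53 when reads outside the 100 most abundant features set the scale, 0.97 outside the most abundant feature and 1.48 with library totals. The share of calls that were rises went from 53.4% with TMM to 72.8%, 85.3% and 92.4% under those scalings, where 3251, 4497 and 5637 features rose and 1216, 778 and 461 fell. By group, the share went from 54.5% to 91.9% in HP8_T1, from 55.3% to 93.2% in HP1_T1 and from 54.0% to 90.4% in HP1_T2 between TMM and library totals. All 2110 rises, and 461 of the 1839 falls, had the same direction under all 6 scalings, and 542 features were called in both directions under different scalings. Every other scaling moved the median upwards from TMM, which favours rises over falls. No scaling that moved it downwards was tried, so the kept counts do not show that rises are firmer than falls. Of the features higher or lower than WT in each hairpin group, 1133 and 254 kept that call under all 6.

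**Figure D3:**
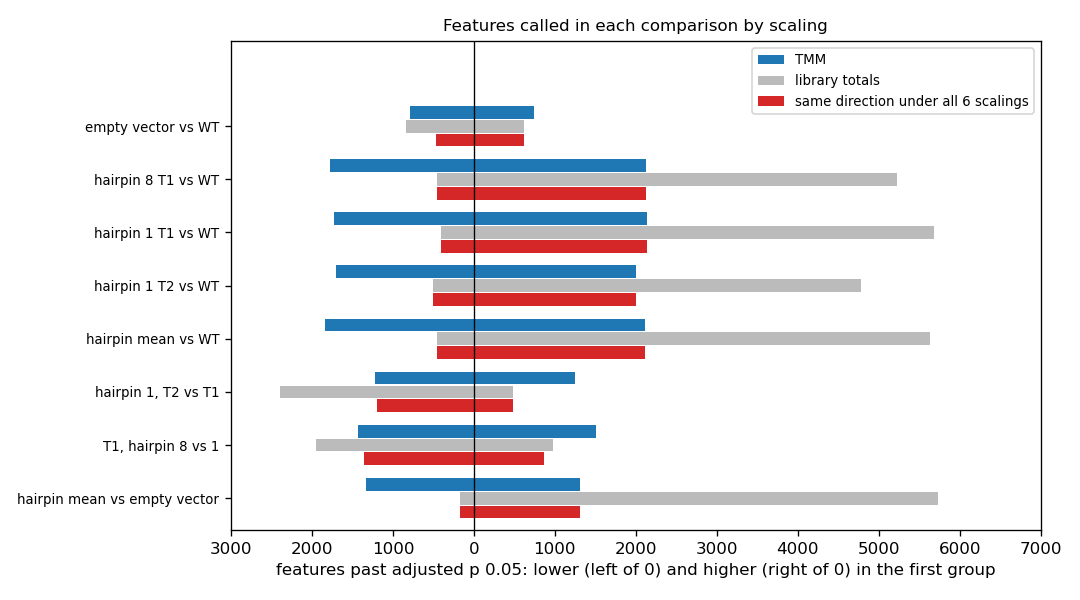
Number of features past an adjusted p of 0.05 in each of the 8 comparisons, with features lower in the group named before "vs" drawn left of 0 and higher features right of 0. Blue bars use TMM, grey bars library totals, and red bars count features called in the same direction under all 6 scalings. In the hairpin mean against WT these are 2110 higher and 461 lower, where every other scaling moved the median change upwards from TMM.

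The 4 features named for their fitted change in the hairpin plants had 0 reads in WT or in all hairpin libraries. Nta#S33577815 (2732 bases) had 0 reads in the 4 WT libraries and 23 in the 4 C libraries, against 464 in HP8_T1, 747 in HP1_T1 and 293 in HP1_T2. This put the pooled hairpin level at least 87.1-fold higher than WT, but the bound does not hold for HP8_T1 or HP1_T2 alone. Their pooled levels were 33.5 and 26.7 CPM, against 0.421 for WT set at 3 reads. The normalised read count of this feature was 33.6 ± 3.71 CPM in HP8_T1, 46.2 ± 1.48 in HP1_T1, 26.6 ± 3.12 in HP1_T2 and 3.90 ± 0.877 in C (SD, n = 4 each). Nta#S36358855 (813 bases) had 0 reads in WT and 2 in C, against 754, 810 and 87 in the same order. This put the pooled hairpin level at least 95.6-fold higher than WT, but the bound does not hold for HP1_T2 alone. The pooled level was 54.4 CPM in HP8_T1, 50.1 in HP1_T1 and 7.94 in HP1_T2, against 0.421 for WT set at 3 reads. Nta#S33541509 (870 bases) had 140 reads in WT and 2 in C, and Nta#S33575445 had 136 in WT and 4 in C; both had 0 in all 12 hairpin libraries. Nta#S33541509 was at least 90.8-fold lower than WT in HP8_T1, 106-fold in HP1_T1 and 71.8-fold in HP1_T2, and Nta#S33575445 at least 88.2-fold, 103-fold and 69.8-fold. The bounds set a group without reads at 3 reads over its 4 libraries and cover counting error only. Adjusted p-values from edgeR's quasi-likelihood test were 1.12e-31, 5.11e-28, 1.70e-29 and 1.04e-29. Passing the threshold and separating all 12 hairpin from all 4 WT libraries were conditions of the choice, so neither is further support. With the same separation and a mean of at least 20 reads per library in the higher group there were 467 higher and 677 lower features.

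**Figure D4:**
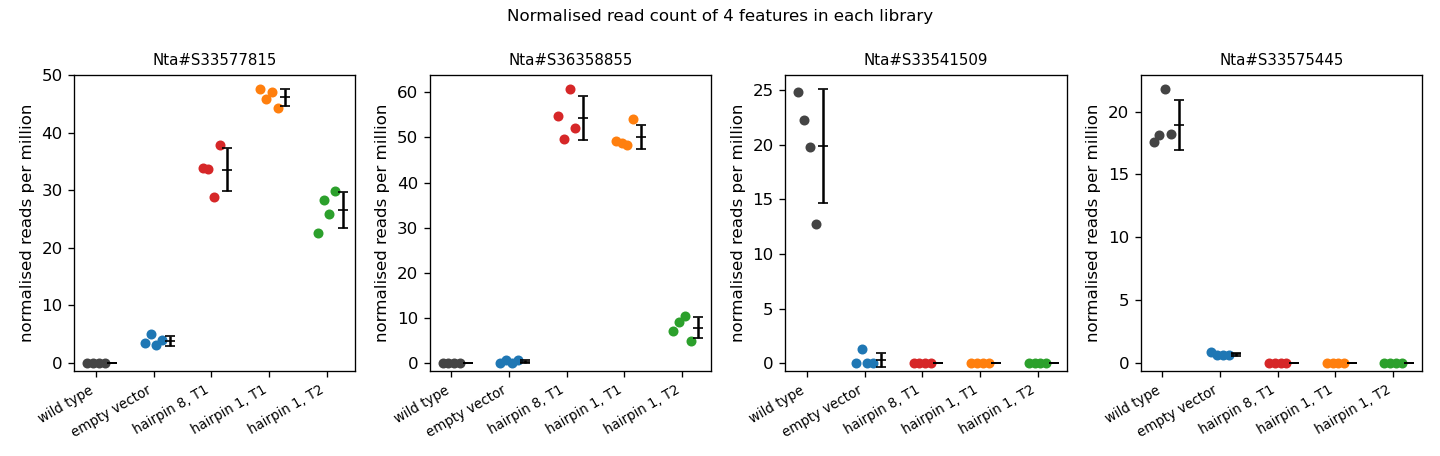
Normalised read count (CPM with TMM factors, fit of all 20 libraries) of 4 features in each library, by group; points are libraries and bars are mean ± SD (n = 4). The left pair has 0 reads in WT and the right pair has 0 reads in the 12 hairpin libraries, and C lies near 0 in all 4 plots compared with the highest group.

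Reads appeared or vanished altogether for few features. There were 17 features with 0 reads in all 4 WT libraries and at least 10 in each of the 12 hairpin libraries, and 4 with the opposite arrangement. Of these 17, 16 had a read in the C libraries, with a median of 27 reads over that group. A count of 0 in WT and C together, with at least 10 reads in every hairpin library, was found for 1 feature. The reverse, 0 reads in every hairpin library and at least 10 in each WT and C library, was found for 0 features.

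Most features that changed in empty-vector plants changed the same way in hairpin plants. Among 7126 features in the fit of all libraries, 1026 were higher than WT both in C and in the hairpin mean, 1105 were lower in both, and 89 were called in opposite directions. Independent lists of these lengths would share 411 higher and 392 lower features. Simulated groups with no change shared 0 in 20 simulations, but at most 1 feature was called there in either comparison, so this 0 sets no scale for the shared counts. The fold changes correlated at 0.746 across features, against 0.616 in simulated groups that share WT and hold no change, so the correlation says little by itself. Their covariance was 0.959 against 0.0549 in those simulations. With the 4 WT libraries split between the comparisons, 597 to 630 features were higher in both and 800 to 822 lower in both. If the WT libraries come from 1 plant or pool, both parts of the split share what is particular to it. Neither the split nor the simulations can then tell a change shared by C and hairpin plants from an unusual WT plant. In C and in each of the 3 hairpin groups, 687 features were higher than WT and 800 were lower. Of these, 687 and 220 kept that call under all 6 scalings. TMM gave the fewest higher and the most lower features of the 6, so these kept counts do not show that rises are firmer than falls.

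The comparison of hairpin with empty-vector plants addressed what goes with the hairpin beyond transformation. The labels give a line and a generation for the hairpin groups but neither for C. A difference in line or generation between C and the hairpin plants therefore cannot be told apart from the hairpin here. Of 7126 features, 1306 rose and 1337 fell in the hairpin mean against C, with 958 rises and 702 falls of at least 2-fold and a median log2 change of 1.43 and −1.03 (median SE 0.29). In each of the 3 hairpin groups, 282 features (3.96%) were higher than both WT and C, and 327 (4.59%) were lower than both. The median log2 change of the 282 features against WT was 2.33 in HP8_T1, 2.37 in HP1_T1 and 2.19 in HP1_T2, against 0.15 in C. For the 327 features it was −2.14, −2.08 and −1.99 in the hairpin groups and −0.65 in C. Nta#S36358855 was higher in the hairpin mean than in C by 6.17 on the log2 scale (SE 0.38, edgeR adjusted p 4.62e-26) and Nta#S33577815 by 3.13 (SE 0.21, adjusted p 3.64e-24), in 12 of 12 hairpin libraries. With library totals, 5734 features rose and 169 fell (97.1% rises against 49.4% with TMM), and 1838 rose and 1007 fell (64.6%) when reads outside the most abundant feature set the scale. Under all 6 scalings, 1306 rose and 169 fell, and the 282 and 46 features of the sets above kept their calls. TMM gave the lowest share of rises of the 6 here too, so these counts do not show that rises are firmer than falls.

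The 2 hairpin lines, compared in the T1 generation, shared most of their changes and also differed from each other. Against WT in the fit of all 20 libraries, 1445 features were higher in both lines and 1245 lower in both, with 84 called in opposite directions. Independent lists would share 629 and 437. The covariance of the fold changes was 1.46 against 0.0553 in simulated unchanged groups, and with WT split between the lines 945 to 988 were higher in both and 980 to 991 lower. Here too, neither check removes what is particular to WT if its libraries come from 1 plant or pool. Tested directly, 1505 features were higher and 1429 lower in HP8_T1 than in HP1_T1, with 756 and 754 at least 2-fold apart. Nta#S33577815 was lower in HP8_T1, with a log2 difference of −0.45 (SE 0.11, edgeR adjusted p 0.000461). Nta#S36358855 differed by 0.13 (SE 0.10, edgeR adjusted p 0.325), which did not pass the threshold. With library totals the split was 980 higher and 1949 lower (33.5% higher against 51.3%), and outside the most abundant feature it was 872 and 2438 (26.3%). The same direction under all 6 scalings was found for 872 and 1356. Over these scalings the median log2 change of all tested features ranged from −0.317 to 0.0121, against −0.0090 with TMM. This favours falls, so the kept counts do not show that falls are firmer than rises.

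Most features that differed from WT in HP1_T1 differed the same way in its progeny HP1_T2. In the same fit, 1427 features were higher in both generations, 1252 lower in both and 52 called in opposite directions. Independent lists would share 596 and 423. The 2 lines HP8_T1 and HP1_T1 shared 1445 and 1245, so this overlap is not particular to parent and progeny. Between the generations, the covariance of fold changes was 1.37 against 0.0551 in simulations. With WT split, 938 to 984 and 968 to 988 features remained shared. The same limit holds for these 2 checks if the WT libraries come from 1 plant or pool. Tested directly, 1245 features were higher and 1225 lower in HP1_T2 than in HP1_T1, with 604 and 711 at least 2-fold apart. Outside the most abundant feature, the 10 most abundant features together took 38.1% ± 0.299 of the reads in HP1_T1 and 48.4% ± 0.392 in HP1_T2 (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0321), against 54.1% ± 0.764 in WT and 48.1% ± 0.672 in C. Among features that separated all 3 hairpin groups from both controls, 23.8% of the 282 higher ones were lower in HP1_T2 than in HP1_T1, towards the controls, and 10.6% were higher still. Over all 7126 features, 17.4% were lower and 16.9% higher in HP1_T2. Among the 1133 features higher than WT in each hairpin group, 15.2% moved towards the controls and 12.1% away from them, and among the 1061 lower ones 28.7% and 11.7%. Of the 327 lower ones, 36.1% moved towards the controls and 10.1% away from them. Under all 6 scalings, 65 and 8 features of the higher set and 61 and 32 of the lower set moved towards and away from the controls. Over these scalings the median log2 change of all tested features between generations ranged from −0.374 to 0.0130, against 0.0057 with TMM. This favours features lower in HP1_T2, so the kept counts cannot compare moves towards and away from the controls. Nta#S36358855 fell by 2.64 on the log2 scale from T1 to T2 (SE 0.15, edgeR adjusted p 1.28e-25) and Nta#S33577815 fell by 0.78 (SE 0.12, edgeR adjusted p 1.32e-07). With library totals 487 features were higher and 2389 lower in T2 (16.9% higher against 50.4%), and outside the most abundant feature 616 and 2294 (21.2%).

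The authors' deposited table of wild-type against hairpin plants listed 967 of 24069 features with a Bonferroni-adjusted p under 0.05, of which 350 were higher and 617 lower in hairpin plants. Of the 967 features in the authors' deposited table, 633 were among those tested here and all 633 were called here in the same direction. The authors' deposited table of wild-type against empty-vector plants listed 147, of which 48 were higher and 99 lower in C, and the 56 of them that were tested here were called in the same direction. The authors' deposited tables rest on different values: the hairpin table on scaled square roots of RPKM and the empty-vector table on unscaled ones. Recomputed on the other kind of value, the hairpin table would list 913 higher and 264 lower features, with 59 higher and 135 lower in the case of the empty vector.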

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

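All tests of explanations given here were chosen after the results were seen. Several measures differed between the hairpin groups by a direct test. HP8_T1 differed from HP1_T1 by −929.2 features detected at equal depth (−305.2 with thinning outside the 100 most abundant features), by 10.4 percentage points in the share of the remaining reads taken by the next most abundant feature and by 8.28 points in the share of the top 10 (exact permutation p = 0.0286 for each). HP1_T2 differed from HP1_T1 by −1577.5 features detected without thinning, by −1181.1 at equal depth (−460.1 with thinning outside the 100 most abundant features), by 7.87 points in the share of the next most abundant feature and by 10.2 points in the share of the top 10 (exact permutation p = 0.0286 for each). In edgeR's test 2934 features differed between the lines and 2470 between the generations. Nta#S33577815 had a log2 difference of −0.45 between HP8_T1 and HP1_T1 and of −0.78 between HP1_T2 and HP1_T1, and Nta#S36358855 one of −2.64 between the generations.

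In 3 of 52 groups of 4 values, 1 library stood apart from the other 3, where chance gives about 1 in 20. The gap over the range was 0.835 for Nta#S36358855 in HP1_T1, 0.840 for Nta#S33575445 in WT and 1.0 for Nta#S33541509 in C, where 1 library had 2 reads and the others 0.

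The share of reads taken by the most abundant feature was higher in C and lower in the hairpin groups than in WT. The order C, WT, hairpin groups held within all 4 replicate numbers. Every group holds each number once, so a run or day marked by the number and acting alike in all groups could not give this order. A run or day that differed between groups was not tested, since the labels give none. A difference in library size is argued against. The lowest C library lay 8.43 percentage points above the highest HP1_T1 library. Mean totals were 2432959 in C and 2450233 in HP1_T1, closer than their spread. Removal of abundant RNA that worked to a different degree in each group cannot be told apart from a difference between the plants, because the files do not name the class of the abundant features; the next most abundant feature took 0.824 times the WT share of the remaining reads in C. An effect of transformation and regeneration with the same sign in C and the hairpin plants is argued against as the whole cause. C lay 5.04 points above WT, and the hairpin groups differed from WT by −5.68 to −8.20. The signs cannot decide on an effect of regeneration that differs between lines or plants. That effect, the transgene and the line of the plants stay open as untested biological explanations.

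WT libraries detected fewer features than all other libraries at equal depth. Depth itself is argued against, since the lowest other library stayed 1623.9 features above the highest WT library after thinning. Reads taken up by a few abundant features could account for part of this gap but not for the whole, because after thinning outside the 100 most abundant features it was still 800.0 features. Passage through tissue culture, which the empty-vector plants share with the hairpin plants, may be a source of the difference and was not tested.

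Between 1526 and 3949 features passed the threshold in each of the 8 comparisons, with only 4 libraries per group. All 30 pairs of libraries of a group differed by more than counting noise (chi-square per degree of freedom at least 1.24), but repeat libraries or runs of fewer RNA samples would too, so these cannot be told apart from separate plants. In every group, pairs 1 and 2 and pairs 3 and 4 were closer to each other (at most 1.38) than the other pairs (at least 1.40). An origin in 1 plant or 1 pool of RNA per group cannot be told apart from separate plants either: the coefficient of variation was 8.91% and no label marks a plant. If so, the calls may reflect differences between single plants as well as between genotypes.

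The real assignment of libraries to groups ranked first among the splits in each comparison, with each library taken as a separate unit. This argues against chance assignment as the source of the counts but does not exclude it, since 1 of 35 is the smallest share that 35 splits allow. Other splits mix the groups, which raises the spread within each side, so their low counts set no scale. Since the labels mark no plants, this does not exclude chance differences between single plants. In fits of the contrasted groups alone, 1 of 35 splits, the real one, reached the real count, with 0 features at most in any other split, for C against WT (1526), HP8_T1 against WT (3048), HP1_T1 against WT (3252), HP1_T2 against WT (2671), HP1_T2 against HP1_T1 (2101) and HP8_T1 against HP1_T1 (2708). For the pooled hairpin libraries the real split was placed among the 100 splits by design, and the others were drawn at random. Only the real split reached the real count, against WT with 3168 features and 0 at most in another split, and against C with 1687 and at most 106.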

How the results depend on the processing

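Counts of calls stayed within 1.5 times the reported value in 167 of 180 alternatives. The 4 named features kept their direction and passed the threshold in every alternative run for them, but they were chosen for the largest fitted changes. Of the 180 alternatives, 80 left out 1 library, and the rule looks at the total count alone, not at which features were called. With library totals, HP8_T1 against WT passed it at 5685 calls, but only 2584 of the 3900 reported calls were kept and 324 were called in the opposite direction. Leaving out 1 library at a time gave 1570 to 1662 calls for C against WT, 3752 to 4020 for HP8_T1, 3694 to 3990 for HP1_T1, 3558 to 3803 for HP1_T2 and 3708 to 4221 for the hairpin mean against WT, 2246 to 2440 between generations, 2723 to 2923 between lines and 2282 to 2765 for the hairpin mean against C, and no call turned direction (0 in each). Without a low-count filter the counts were 4875, 7862, 7862, 7322, 7974, 4719, 5553 and 4569 in the same order, as up to 20394 features were then tested. Library totals, a scaling added after seeing the data, gave 6098 for HP1_T1 against WT, 6098 for the hairpin mean against WT and 5903 for the hairpin mean against C; there the median of all features moved up to 1.48 for the hairpin mean against WT. The fit of all 20 libraries, also added later, gave 2893 for C against WT and kept 1320 of the 1526 calls. It tested 7126 in place of 2782 features and also changed the libraries, the dispersion and the TMM factors, and the cause was not tested. With WT split between comparisons, features called alike in C and the hairpin mean fell from 2131 to between 1415 and 1441, with fewer WT libraries in each fit. Without thinning, C had −33.5 features against WT in place of 1779.15 at equal depth, since C had the fewest reads outside the most abundant feature; thinning outside the 100 most abundant features gave 1055.5 for C, 1438.2 for HP8_T1, 1743.4 for HP1_T1 and 1283.3 for HP1_T2 against WT, in place of 1779.15, 2290.2, 3219.4 and 2038.3. With a replicate block the counts were 1534, 3927, 3885, 3744, 3983, 2516, 2993 and 2672, and no count moved by over 1.5 times. Same-numbered libraries deviated together with correlations of −0.127 to 0.400 (median 0.133, 40 pairs, 329 features with a mean of at least 100 reads). The median was −0.0472 in 120 pairs of different numbers. In all 4 other groups, 5 of 20 libraries correlated best with their own number. These values point to a factor shared by libraries of 1 number, which the labels do not name. The reported fits leave it out, and the replicate block takes it up. Differences within replicate numbers, added after seeing the data, gave an exact p of 0.125 in place of 0.257 between lines and 0.571 between generations for the share of the most abundant feature. A fit of the contrasted groups alone is the reported fit for C against WT and for the hairpin mean against WT. Alternatives for normalized values and gene lists were not run, because counts were used and the files do not pair identifiers with names. DESeq2's test gave 1268 to 3665 calls per comparison, within 1.5 times of edgeR's.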

Other observations

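Some features set the empty-vector plants apart from all others. By edgeR's test in the fit of all 20 libraries, 176 features were higher in C than in WT and in each hairpin group. Another 186 were lower in C than in WT and in each hairpin group. Of these, 7 and 99 kept their calls under all 6 scalings. Every other scaling moved the median change of the hairpin mean against C upwards from TMM. That favours features lower in C, so the kept counts do not show that these are firmer. A further 504 features were higher and 376 lower in C than in WT without passing the threshold between C and any hairpin group, which does not show that these levels were equal. Under all 6 scalings, 15 and 6 features met that description. Features with 0 reads in all 4 WT libraries and at least 10 in each C library numbered 4, and 3 features had 0 reads in C and at least 10 in each WT library.

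With TMM scaling, the direction of change went with abundance. Among the 9 features ranked 2 to 10 outside the most abundant feature, 2 were higher and 7 lower in the hairpin mean than in WT, and among the 90 ranked 11 to 100, 30 were higher and 53 lower. Of the 6125 tested features beyond the 1000 most abundant, 1731 were higher and 1444 lower. The other scalings, not run for these classes, moved the median of all features upwards, which favours rises in every class. The log2 change went weakly with feature length, with a Spearman correlation of −0.0675 across 7126 features, which are not independent replicates. The median length was 883 bases among features higher in the hairpin mean, 895 among lower ones and 885 among those not called.

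In all 5 groups the share of the most abundant feature was highest in replicate 1, followed by replicates 2, 4 and 3. Pairs of libraries numbered 1 and 2 or 3 and 4 differed less (chi-square per degree of freedom 1.24 to 1.38 in 10 pairs) than the other 20 pairs (1.40 to 2.05). The labels give no run, lane or day for these numbers.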
